A study of Mus musculus with 10 samples.

How the data were processed

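Total RNA of whole colon from wild-type C57BL/6 mice was measured by bulk RNA sequencing in 10 libraries, 5 of the stress group and 5 of the control group, per the labels. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the stranded Illumina TruSeq mRNA kit, which reads mostly polyadenylated RNA, and sequencing was run on an Illumina NextSeq instrument. The stress and control groups were taken from the treatment named in the labels, and the replicate number from the title of each sample. The labels do not say whether the 5 libraries of a group came from separate mice, so all p-values measure only the spread between these samples, which may in part be technical.

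The authors deposited for each library estimated counts and TPM per transcript, both made with kallisto 0.46.0, per the file headers and the run record of each library. Per those run records, kallisto ran on single-end reads with a stated fragment length of 296 bases, an SD of 20 bases and 30 bootstraps, and no strand option was set. Kallisto matches reads to transcripts without base-level alignment and divides a read that fits several transcripts among them, so its estimated counts need not be whole, and the members of near-identical gene families and the genes whose exons overlap on opposite strands are less certain one by one than the rest. The genome build and the annotation release behind the index are not given in the sources used here. Each library came with a pair of tables, which held the same values to within a relative difference of 5.00e-06.

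The tables list 119215 transcripts, of which 116384 matched the GENCODE M21 annotation (GRCm38) by identifier and version, 388 matched without the version, and 2443 did not match. The unmatched transcripts held 0.908 to 1.16% of the counts of a library and were left out. Of the transcripts matched with their version, 100% had the same length in the files and in that annotation. Gene names and coordinates are those of GENCODE M21 on GRCm38. The estimated counts were summed per gene over 35969 genes, of which 92 share a symbol with another gene and were kept apart by identifier, and the sums were rounded to whole numbers.

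Reads pseudoaligned per library ranged from 2100452 to 8666987. The floor of 3 counts, the upper limit that a count of 0 allows at 95% confidence, was 0.349 to 1.44 CPM (counts scaled to a common library total), depending on the library. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. All pairs of libraries within a group were compared before averaging: over 20 pairs, the chi-square statistic per degree of freedom was 6.25 to 27.6 and the correlation of log2 CPM was 0.930 to 0.984, so no library was a copy of another of its group.

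Differences between stress and control were tested with edgeR 4.0.16 (quasi-likelihood F test) under R 4.3.3, after TMM scaling and edgeR's own filter for low counts by group, which left 13062 genes. P-values were adjusted by the method of Benjamini and Hochberg, and 0.05 was the threshold on the adjusted p. Gene levels are given as TMM-scaled CPM, as mean ± SD over the 5 libraries of a group. Sums of CPM over marker lists and the CPM of skeletal muscle genes, neutrophil genes and Hoxd13 are without TMM scaling. The biological coefficient of variation was 16.65%. Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and again with the estimated correlation and with fry. Of 56 lists, 51 entered that test. Of the others, 4 had under 4 tested members, and 1 served only to check samples. A list score is the mean over its tested genes of log2 CPM, each gene relative to its mean over the 10 libraries. Scores and single values were compared between groups by exact two-sided permutation tests over all 252 assignments, whose smallest possible p is 0.00794. Correlations across libraries were tested with 100000 permutations.

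The main tests, the gene lists, 18 fixed genes and the alternatives listed as planned were set before the data were examined. The genes named in the text are the 18 fixed genes; the 10 largest rises and the 10 largest falls in log2 fold change among genes past the threshold with a mean of at least 1 CPM, without predicted genes, pseudogenes or variable segments of antigen receptors; and, of each list past its threshold, the up to 4 tested members with the smallest p in the direction of the list and up to 2 members past the threshold in the opposite direction. Genes named outside that rule are said to be so. Some genes that the rule takes in are not reported here. Of 87 named genes that were tested, 19 have exons that overlap those of another gene in GENCODE M21, and for 5 of them (Arg2, B3galt2, Mndal, Plin4 and Sh2d7) the overlapping gene held at least 5% as many counts.

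The alternatives were other scalings (DESeq2 size factors, upper quartile), other filters, an offset for transcript length, log2(TPM + 0.5) and log2(TPM + 0.1) with limma, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, limma voom with sample weights, a threshold of 0.1, a test against a fold of 1.2, and the other list tests. Added after the data were seen were a GC correction, which subtracts from each library a lowess trend (span 0.3) of log2 CPM on the GC content of the longest transcript of each gene, and fits without pairs or sets of libraries. GC content was known for 99.8% of the tested genes.

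The pipeline was tested on simulated counts with the means and depths of the real libraries. With 5 libraries per group and 12918 genes tested, 32.8% of 67 genes changed 1.5-fold were called, 86.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold. Of the calls, 6.45% of 155 were false, and 0 genes were called when nothing was changed. With the fitted GC trends imposed, 148 of 200 genes changed 2-fold were called without the GC correction and 160 with it, beside 10 unchanged genes in each case. When 1 list was raised 1.3-fold, it alone was called among 50 lists tested, in counts drawn independently between genes, so that the list test was not checked for correlated genes.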

Results

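Whole colon was profiled in mice after 7 days of daily restraint, a rodent model of psychological stress in which the animal is held in a narrow space, and in control mice. The series is about the enteric nervous system, the neurons and glia of the gut wall, as a link from stress to gut inflammation. The comparison asks what restraint does to gene expression in the whole colon. The 5 control libraries held 2890548, 7135416, 4811510, 8666987 and 3905477 pseudoaligned reads (replicates 1 to 5). The 5 stress libraries held 8238506, 3208000, 6953934, 4588523 and 2100452. Of all reads, 77.2 to 83.8% were pseudoaligned, and 11550 to 14121 genes per library had at least 10 counts.

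Among genes past the threshold, those of sterol synthesis and of the epithelial oxidase system had some of the largest rises under stress. Mvd, which encodes an enzyme of the mevalonate pathway, rose from 19.8 ± 4.80 CPM in controls to 44.3 ± 5.51 CPM under stress (SD, n = 5 per group). Its log2 fold change was 1.18 (SE 0.163, adjusted p = 0.0157, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Mvk, of the same pathway, rose by 1.12 (SE 0.190, adjusted p = 0.0261). Duox2, a hydrogen peroxide producing oxidase of the gut epithelium, rose from 81.7 ± 18.8 to 147 ± 29.1 CPM (log2 fold change 0.86, SE 0.162, adjusted p = 0.0486). Its maturation factor Duoxa2 rose from 18.0 ± 6.25 to 42.6 ± 12.3 CPM (1.28, SE 0.242, adjusted p = 0.0487). Socs3, an inhibitor of cytokine receptor signalling that such signals induce, rose from 10.1 ± 2.04 to 22.4 ± 3.95 CPM (1.16, SE 0.165, adjusted p = 0.0160). Other large rises were those of the lipoprotein receptor gene Lrp8 (1.32, SE 0.246, adjusted p = 0.0479), the RNase gene Zc3h12a (0.97, SE 0.188, adjusted p = 0.0487), the clock gene Per2 (0.94, SE 0.172, adjusted p = 0.0437) and the peroxidase gene Lpo (0.89, SE 0.148, adjusted p = 0.0238). For each of the genes named here, all 5 stress libraries lay above all 5 control libraries.

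Among genes past the threshold over all genes, a cluster of gasdermin genes and a phospholipase gene had the largest falls. Gsdmc2, of a family of pore-forming proteins, fell from 805 ± 199 to 317 ± 33.8 CPM (log2 fold change -1.34, SE 0.155, adjusted p = 0.00393). Gsdmc3 fell from 256 ± 18.5 to 120 ± 22.8 CPM (-1.09, SE 0.125, adjusted p = 0.00393) and Gsdmc4 from 842 ± 133 to 389 ± 77.0 CPM (-1.11, SE 0.154, adjusted p = 0.0157). These neighbours on chromosome 15 (63824346 to 63912297, GRCm38) are near-identical, so the division of reads among them is uncertain. The 4 members summed fell from 1900 ± 337 to 831 ± 127 CPM (-1.19, SE 0.146, adjusted p = 0.0158). Pla2g4c, which encodes a cytosolic phospholipase A2, fell from 11.6 ± 5.73 to 2.69 ± 1.14 CPM (-2.15, SE 0.383, adjusted p = 0.0353). Control 1, at 2.79 CPM, lay among the stress libraries. The C-type lectin gene Clec2e fell from 158 ± 35.4 to 76.0 ± 11.6 CPM (-1.05, SE 0.152, adjusted p = 0.0174). The arginase gene Arg2 fell from 16.8 ± 2.27 to 8.72 ± 2.08 CPM (-0.99, SE 0.165, adjusted p = 0.0238). B3galt2 (-0.96), Mndal (-0.85), Ice2 (-0.67) and the carboxylesterase gene Ces2b (-0.66) fell with adjusted p between 0.0238 and 0.0487. Exons of Arg2 and B3galt2 overlap those of Vti1b and Cdc73 on the opposite strand, and exons of Mndal those of its relative Ifi203. Their counts are therefore less certain. Apart from Pla2g4c, all 5 stress libraries lay below all 5 controls for each of these 10 genes.

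In all, 41 of 13062 genes passed the threshold, 29 higher and 12 lower under stress, beside 1957 with an unadjusted p under 0.05. The genes past it that the naming rule left out, named after their values were seen, included Fasn (0.85), Acat2 (0.86), Aacs (0.85) and Scd2 (0.79) of lipid synthesis, Lig1 (0.68), Dnmt1 (0.63) and Uhrf1 (0.72), which act at DNA replication, and the clock gene Per3 (0.46). The count rested on single libraries. Leaving out 1 control gave 6 (control 1), 4 (control 2), 27 (control 3), 4 (control 4) and 100 (control 5). Leaving out 1 stress library gave 2 (stress 1), 32 (stress 2), 4 (stress 3), 89 (stress 4) and 23 (stress 5). None of the 41 changed sign in these fits, and only Gsdmc2 and Gsdmc3 stayed past the threshold without any 1 of the 10 libraries. It was 270 with DESeq2 and 314 with limma voom. It was 5 with an offset for transcript length and 4 on the log2(TPM + 0.5) scale, where 0 of the rises passed and Gsdmc2, Gsdmc3 and Gsdmc4 still did. Without control 5 and stress 4 together, left out after the data were seen, it was 961, and the split of the 10 libraries that exchanges this pair gave 1679, but 6 gene lists past their threshold against 14 with the labels as given. After a GC correction that split gave 96 genes and 14 lists, against 115 genes and 16 lists with the labels as given. That split also sorts the libraries by the slope of their log2 CPM on GC content, described below. So do the given labels once control 5 and stress 4 are left out. The counts of 961 and 1679 therefore cannot be told apart from that slope.

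**Figure D1:**
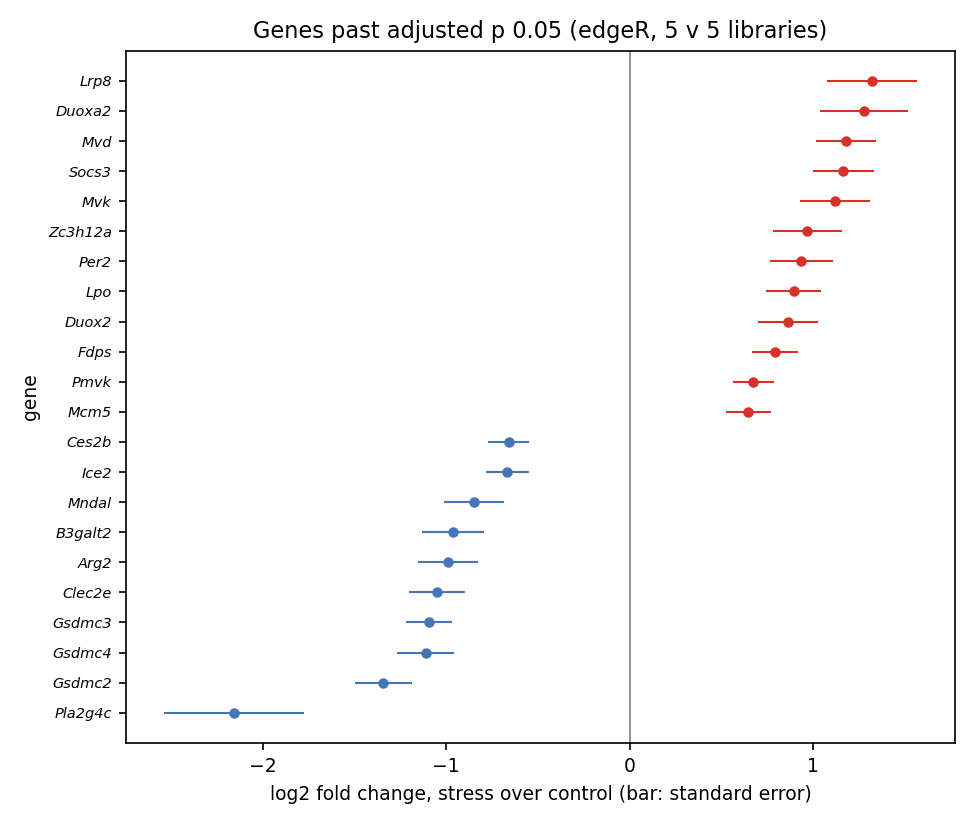
Log2 fold change, stress over control, of 22 genes past the threshold of 0.05 on adjusted p, one gene per line, and bars are standard errors of the edgeR fit over 5 and 5 libraries. Genes higher under stress (red) include Mvd at 1.18, and the lower genes (blue) reach -2.15 for Pla2g4c.

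**Figure D2:**
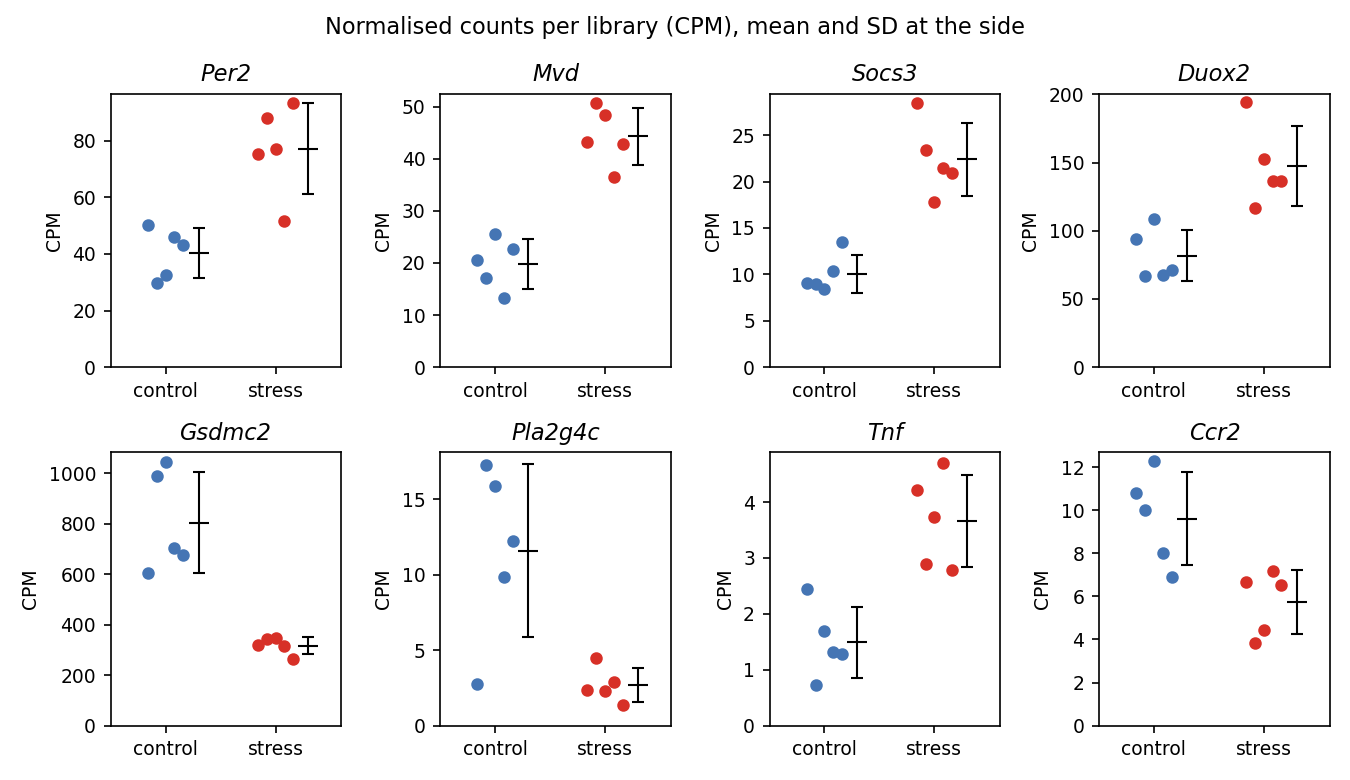
TMM-scaled CPM in each of the 5 control (blue) and 5 stress (red) libraries for 8 genes, with the group mean and SD at the side, and each vertical axis starts at 0. Gsdmc2 lay between 263 and 348 CPM in the stress libraries and between 607 and 1046 CPM in the controls.

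The cholesterol synthesis list rose as a group. All 21 of its tested genes had a positive log2 fold change (mean 0.65, adjusted p = 5.50e-17, camera). Its score separated the 5 stress from the 5 control libraries (exact permutation p = 0.00794, the smallest possible, 0.101 adjusted over the 51 lists). With an estimated correlation between genes the list did not pass (adjusted p = 0.240 with an estimated correlation). Fry, which asks only whether its genes moved one way, gave an adjusted p of 0.0126. Of its members 8 rose over all genes, and 18 rose when adjusted over the list alone. Mvd, Pmvk (0.67, SE 0.110, adjusted p = 0.0238) and Fdps (0.79, SE 0.127, adjusted p = 0.0238) had some of the smallest p. Pmvk lost its call after the GC correction (0.50, SE 0.142, adjusted p = 0.119).

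The antimicrobial and epithelial defence list, the cell cycle list and the hypoxia and glycolysis list also rose. In the defence list (mean 0.37 over 18 tested genes, adjusted p = 0.00192, camera, adjusted p = 0.586 with an estimated correlation), Duox2 and Duoxa2 rose over all genes. Adjusted over the list alone, 9 genes rose and 2, Itln1 and Ang4, fell. The scores did not separate the groups (exact permutation p = 0.143). Stress 1 (0.41) and stress 2 (0.61) lay above every control, and the other stress libraries, at -0.07 to -0.05, lay below control 3 (0.35). The mean of the list was 0.17 without stress 2 and 0.58 without control 3. Reg3b, which encodes an antimicrobial lectin, had the largest positive log2 fold change of the list, 2.52 (SE 0.501, adjusted p = 0.0539). It went from 539 ± 576 CPM in controls to 3085 ± 1204 CPM under stress, with control 3 at 1567 CPM and the 5 stress libraries above all controls. The 3 tested Reg3 genes, which are close relatives, gave 2.39 when summed (SE 0.507, adjusted p = 0.0677). Nos2, the inducible nitric oxide synthase gene, had a log2 fold change of 2.19 (SE 0.482, adjusted p = 0.0744). Reg3b passed after the GC correction (adjusted p = 0.0297) and Nos2 did not (adjusted p = 0.0533). In the cell cycle list (mean 0.25 over 25 genes, 23 of them positive, adjusted p = 0.00110, camera, adjusted p = 0.586 with an estimated correlation), Mcm5, part of the replicative helicase, rose (0.65, SE 0.124, adjusted p = 0.0487). Stress 5 had a score of -0.46, below every control (the lowest at -0.36), and the scores did not separate the groups (exact permutation p = 0.246). The call was lost without control 5 and stress 4 together (adjusted p = 0.149). Adjusted over the list alone 7 genes rose, among them Pcna (0.37, SE 0.0824), Mcm2 (0.50, SE 0.114) and Mcm6 (0.44, SE 0.107), with adjusted p over all genes of 0.0755, 0.0830 and 0.108. In the hypoxia and glycolysis list (mean 0.12 over 19 genes, adjusted p = 0.0470, camera, adjusted p = 0.630 with an estimated correlation), 1 gene, Hk2 (0.61, SE 0.139), rose when adjusted over the list alone and 0 rose over all genes. Ndrg1 (0.30), Pgam1 (0.22) and Slc2a1 (0.25) had adjusted p of 0.183 to 0.373. That last list lost its call after the GC correction (mean 0.08, adjusted p = 0.128), without stress 2 and stress 5 together (mean 0.05, adjusted p = 0.337), and without any 1 of control 2, control 3, control 4, stress 1, stress 2, stress 3 or stress 5 (adjusted p 0.0551 to 0.166).

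Lists of lymphocytes, of MHC class II presentation and of interferon-stimulated genes fell. All 10 tested genes of the T and NK cell list were lower (mean -0.50, adjusted p = 7.29e-04, camera, adjusted p = 0.251 with an estimated correlation, fry adjusted p = 0.0380). The score separated the groups (exact permutation p = 0.00794, the smallest possible, 0.101 adjusted over the 51 lists). Gzma (-0.81, SE 0.238, adjusted p = 0.170) was its only member to fall when adjusted over the list alone. Cd8a (-0.60), Cd4 (-0.64) and Cd3g (-0.53) had adjusted p of 0.221 to 0.316. All 11 tested genes of the B cell list were lower (mean -0.76, adjusted p = 0.00112, camera, adjusted p = 0.586 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. Among the smallest p were those of Ms4a1 (-0.93, SE 0.331), Cd22 (-1.04, SE 0.422) and Cd79a (-1.04, SE 0.440). Without control 5 and stress 4 together the mean of the B cell list was -0.43 and its call was lost (adjusted p = 0.243, and 0.0506 with the GC correction). In the plasma cell list (mean -0.28 over 16 genes, adjusted p = 0.0389, camera, adjusted p = 0.586 with an estimated correlation), 3 genes fell when adjusted over the list alone. The immunoglobulin joining chain gene Jchain, at 557 ± 62.3 CPM in controls and 344 ± 77.3 CPM under stress, had an adjusted p over all genes of 0.0678 (-0.69, SE 0.147). Igkc (-0.38), Pou2af1 (-0.66) and Ighg1 (-0.97) followed. The MHC class II list (9 genes, all lower, mean -0.41, adjusted p = 0.00716, camera, adjusted p = 0.586 with an estimated correlation) held H2-Eb1 (-0.44), H2-Aa (-0.49), H2-Ab1 (-0.45) and H2-DMb2 (-0.72), none past the threshold. The MHC class I list did not pass (mean 0.08, 8 of 12 genes positive, adjusted p = 0.468), and its mean was -0.00209 after the GC correction. Of 25 interferon-stimulated genes 23 were lower (mean -0.30, adjusted p = 7.29e-04, camera, adjusted p = 0.630 with an estimated correlation), among them Ddx58 (-0.38), Oasl2 (-0.53), Gbp3 (-0.54) and Rtp4 (-0.47), with 0 past the threshold over all genes or adjusted over the list alone. The mean of this list was -0.18 without control 2 or without stress 3 and -0.46 without stress 2. The MHC class II list lost its call without control 5 (adjusted p = 0.0662). The plasma cell list lost its call without any 1 of control 1, control 3, control 5, stress 3 or stress 4 (adjusted p 0.0588 to 0.167).

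The tuft cell and fatty acid oxidation lists fell with scores that separated the groups (exact permutation p = 0.00794 each, the smallest possible, and 0.101 each when adjusted over the 51 lists). In the tuft cell list, markers of a chemosensory epithelial cell, 10 of 11 genes were lower (mean -0.34, adjusted p = 0.00536, camera, adjusted p = 0.256 with an estimated correlation, fry adjusted p = 0.0407), and 3 fell when adjusted over the list alone. Rgs13 (-1.05, SE 0.253), Sh2d7 (-0.69, SE 0.207) and Plcb2 (-0.56, SE 0.185) had adjusted p over all genes of 0.104 to 0.214. In the fatty acid oxidation list (mean -0.17 over 19 genes, adjusted p = 0.00716, camera, adjusted p = 0.586 with an estimated correlation), 6 genes fell when adjusted over the list alone, among them Pdk4, which restrains the use of pyruvate (-0.95, SE 0.209, adjusted p over all genes 0.0744), Hadhb (-0.34, SE 0.0866), Etfdh (-0.34, SE 0.0891) and Acadm (-0.32, SE 0.0867). It lost its call without stress 4 (adjusted p = 0.107) and without control 5 and stress 4 together (adjusted p = 0.204). After the GC correction Hadhb was at -0.16 (adjusted p over all genes 0.477, edgeR), Etfdh at -0.23, Acadm at -0.28 and Pdk4 at -0.88.

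Lists of excitatory and sensory neurons, adipocytes and extracellular matrix fell as well. Of the 8 tested neuron genes 7 were lower (mean -0.49, adjusted p = 0.0143, camera, adjusted p = 0.586 with an estimated correlation), and 3 fell when adjusted over the list alone. The neuropeptide genes Nmu (-1.19, SE 0.299), Grp (-1.05, SE 0.281) and Penk (-0.31, SE 0.183) and the calcium-binding protein gene Calb2 (-0.47, SE 0.164) had adjusted p over all genes of 0.115 to 0.435. The call was lost without control 3 (adjusted p = 0.0977) and without stress 3 (adjusted p = 0.0863), and without a filter the mean was -0.31. The adipocyte list, which marks fat attached to the gut (mean -0.49 over 10 genes, adjusted p = 0.0346, camera, adjusted p = 0.586 with an estimated correlation), had 0 members past the threshold over all genes or adjusted over the list alone. Adipoq was at 23.4 ± 15.5 CPM in controls and 8.63 ± 9.53 CPM under stress (-1.46, SE 0.619, adjusted p = 0.292). Fabp4 (-0.79), Plin4 (-0.65) and Acvr1c (-0.44) followed. In the extracellular matrix list (mean -0.13 over 19 genes, adjusted p = 0.0470, camera, adjusted p = 0.690 with an estimated correlation), 3 genes fell when adjusted over the list alone. Sparc (-0.38, SE 0.0941, adjusted p over all genes 0.111), Fbn1 (-0.46), Col3a1 (-0.38) and Postn (-0.31) had the smallest p. After the GC correction Postn was at -0.10 (adjusted p over all genes 0.619, edgeR), Sparc at -0.43, Fbn1 at -0.51 and Col3a1 at -0.42. The adipocyte call was lost without any 1 of control 1, control 2, stress 1 or stress 4 (adjusted p 0.0528 to 0.150), and without control 2 the mean was -0.28. The matrix call was lost without any 1 of control 2, control 3, control 5, stress 1, stress 2 or stress 4 (adjusted p 0.0569 to 0.301). The mean of the matrix list was -0.07 without control 3, -0.08 without stress 1 and -0.21 after the GC correction.

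In all, 14 of 51 lists passed with the preset correlation, 4 up and 10 down. Of these, 0 passed with an estimated correlation and 3 with fry (cholesterol synthesis, T and NK cells, tuft cells). The count of 14 lists was also reached by 10 of 100 splits of the 10 libraries into 5 and 5, the real one included. The scores of the 10 lists other than cholesterol synthesis, T and NK cells, tuft cells and fatty acid oxidation had exact permutation p of 0.0159 to 0.246, and no score passed after adjustment over the 51 lists.

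**Figure D3:**
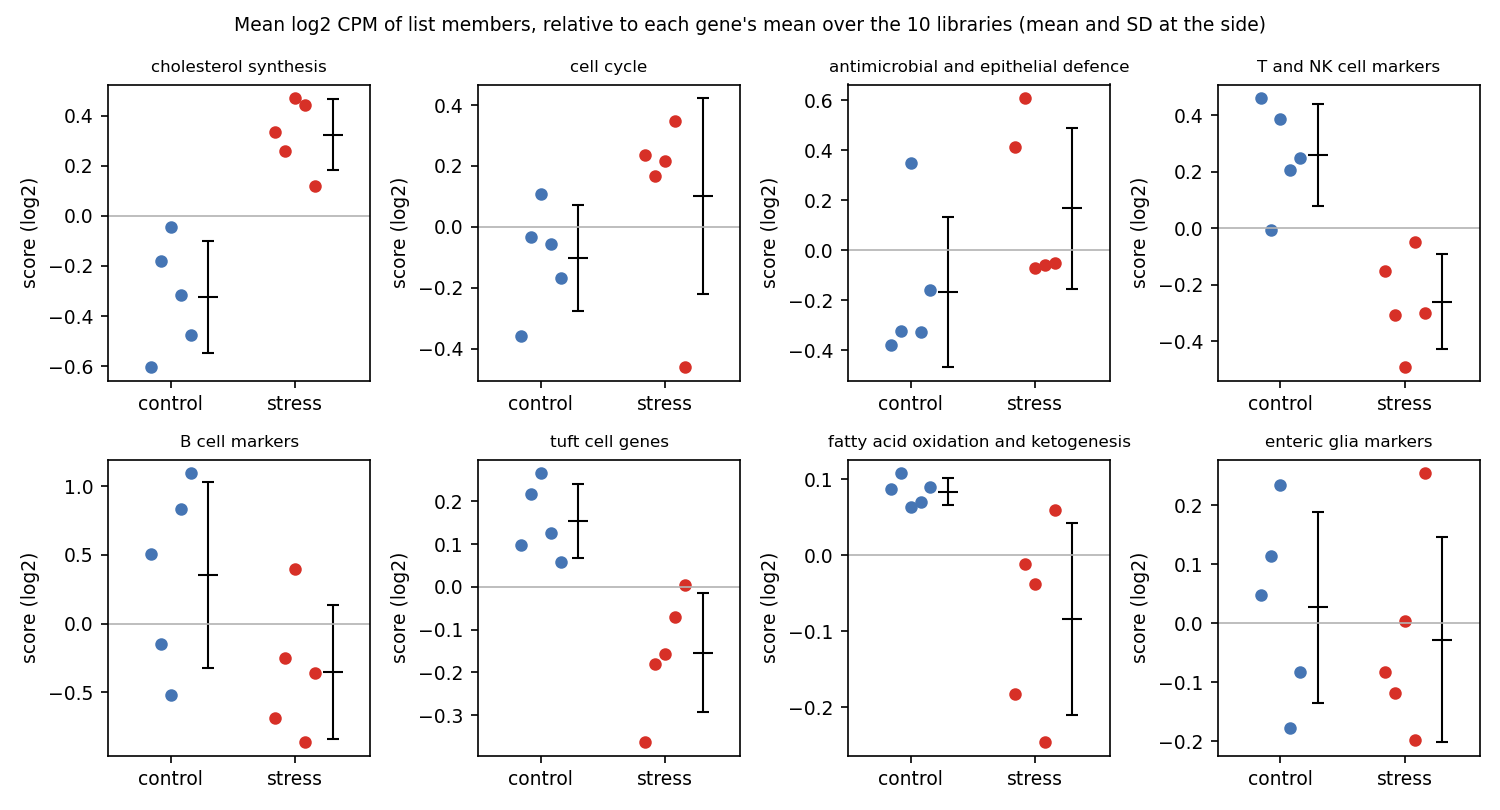
Score of 8 gene lists in each control (blue) and stress (red) library, as the mean log2 CPM of the tested members relative to each gene's mean over the 10 libraries, with the group mean and SD at the side. The 5 stress and 5 control libraries do not overlap for the cholesterol synthesis, T and NK cell, tuft cell and fatty acid oxidation lists, and they overlap for the enteric glia list.

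Other lists close to the subject of the series did not pass in the main test. The NF-kB target list had a mean of 0.23 (adjusted p = 0.0538, camera) and the list of inflammatory cytokines and chemokines a mean of 0.46 over 9 tested genes (adjusted p = 0.156). The score of the cytokine list was 0.62 in stress 1 and 0.33 in stress 4. It was -0.18 to 0.02 in the other stress libraries and -0.44 to 0.08 in the controls. Over the alternatives the mean of that list was 0.28 to 0.54. Genes that glucocorticoids induce had a mean of -0.08 (adjusted p = 0.291). Adjusted over the list alone, 2 of their 25 tested members rose and 3 fell. Without stress 2 and stress 5 together the mean was -0.17 and this list passed with the preset correlation (adjusted p = 0.0168) but not with an estimated one (adjusted p = 0.525 with an estimated correlation). Enteric neuron markers (-0.08, adjusted p = 0.337), enteric glia markers (-0.08, adjusted p = 0.732), acetylcholine signalling genes (0.06, adjusted p = 0.394), monocyte markers (-0.13, adjusted p = 0.442) and macrophage markers (-0.14, adjusted p = 0.117) did not pass against the other genes. Over the alternatives the mean was -0.16 to -0.02 for the enteric neuron list and -0.15 to 0.02 for the enteric glia list. The macrophage score had an exact permutation p of 0.0476 (0.258 adjusted over the 51 lists), and after the GC correction it separated the groups (exact permutation p = 0.00794, the smallest possible, 0.0810 adjusted). The clock list had a mean of 0.05 (adjusted p = 0.594), although Per2 and Per3 rose. Adjusted over the list alone, 4 of its 18 tested genes rose and 1 fell. A mean over genes that move in opposite directions cannot show whether the clock shifted. The smooth muscle list had a mean of 0.00, a median of -0.02 and the direction down in camera (adjusted p = 0.921). The NF-kB list passed in 10 of 25 alternatives with the preset correlation. These were upper-quartile scaling (adjusted p = 0.0478), no filter (0.0239), a filter of 1 CPM (0.0457), the length offset (0.0189), log2(TPM + 0.5) (0.0146), leaving out control 1 (0.0377), control 5 (0.0323) or stress 4 (0.0397), and leaving out control 5 and stress 4 together without (0.0300) or with the GC correction (0.0145). With an estimated correlation it passed in none of these 10, nor in the main setting (adjusted p = 0.390 to 0.766 and 0.586 with an estimated correlation). The macrophage list passed without a filter (0.0262) and without control 4 (0.0337), but not with an estimated correlation (adjusted p = 0.534 and 0.465 with an estimated correlation). After the GC correction the lists of glucocorticoid-induced genes (adjusted p = 0.0160), macrophage markers (adjusted p = 0.0160) and enteric neuron markers (adjusted p = 0.0449) passed, all downward. With an estimated correlation after the same GC correction none of these 3 lists did (adjusted p = 0.476, 0.476 and 0.523 with an estimated correlation).

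Among 18 genes fixed for what the series is about, 15 were tested and 0 passed over all genes, but Tnf and Ccr2 passed when adjusted over the list alone. Tnf, the gene of a central inflammatory cytokine (chromosome 17, 35199381 to 35202007, GRCm38), rose from 1.49 ± 0.634 CPM in controls to 3.66 ± 0.828 CPM under stress (SD, n = 5, log2 fold change 1.44, SE 0.295, adjusted p = 0.0605 over all genes and 0.00375 adjusted over the list alone), with all 5 stress libraries above all 5 controls. Ccr2, the receptor by which monocytes follow the chemokine CCL2 (chromosome 9, 124101950 to 124113557), fell from 9.60 ± 2.16 to 5.73 ± 1.48 CPM (-0.73, SE 0.216, adjusted p = 0.172 over all genes and 0.0344 adjusted over the list alone). Csf1, a growth factor of macrophages, was at 8.81 ± 2.36 and 11.02 ± 1.14 CPM (0.37, SE 0.182, adjusted p = 0.347 over all genes and 0.176 adjusted over the list alone). Ly6c2, a monocyte marker, was at 6.79 ± 0.842 and 5.88 ± 2.05 CPM (-0.16, SE 0.231, adjusted p = 0.582 adjusted over the list alone). The glia genes S100b (-0.60) and Gfap (-0.23), the neuron genes Elavl4 (-0.41), Ret (-0.26) and Nos1 (0.02), the growth factor gene Tgfb2 (0.60), the glucocorticoid receptor gene Nr3c1 (-0.14) and its targets Tsc22d3 (-0.37), Fkbp5 (-0.12) and Per1 (0.07) had p between 0.0984 and 0.911 adjusted over the list alone. Ccl2, Chat and Sox10 did not reach the filter, with 10, 27 and 42 counts in the controls and 29, 33 and 47 under stress. They were not tested in this fit. Tnf stayed past the threshold adjusted over the list alone without any 1 library. Ccr2 did not pass without control 1 (0.0580), control 2 (0.0891), control 3 (0.116), stress 2 (0.0894) or stress 3 (0.130), nor after the GC correction (0.0736). Over all genes Tnf passed after the GC correction, chosen after the data were seen (adjusted p = 0.0392, edgeR), but in 0 of the fits without 1 library.

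The libraries differed among themselves along the GC content of genes. The first principal component held 38.0% of the variance and followed the slope of log2 CPM on GC content across the 10 libraries (Pearson's r = 0.994, permutation p = 1e-05, the smallest possible, Spearman's rho = 0.988, permutation p = 1e-05, r = 0.986 without the 2 farthest libraries, r = 0.982 within controls and 0.999 within stress). The slope fell as the share of mitochondrial counts rose (r = -0.942, permutation p = 1.60e-04, rho = -0.939, permutation p = 2.10e-04, r = -0.925 without the 2 farthest). Its relation to depth was weaker (r = -0.629, permutation p = 0.0550, rho = -0.649, permutation p = 0.0479, r = -0.320 without the 2 farthest, so that it rests on those libraries). Over these 3 relations the adjusted p of r were 3e-05, 2.40e-04 and 0.0550. Between the groups neither the slope (exact permutation p = 0.159) nor the mitochondrial share (12.0 ± 2.13% in controls, 10.5 ± 3.01% under stress, SD, n = 5, exact permutation p = 0.365) differed by more than the spread. Over all tested genes the log2 fold changes nevertheless rose with GC content (Spearman's rho = 0.511 across genes, which are not independent replicates, 0.0196 after the GC correction). The 29 genes past the threshold that were higher under stress had a GC content of 48.6 to 59.0%, against 35.5 to 47.2% for the 12 lower ones. With the GC correction, chosen after the data were seen, 115 genes passed, 75 higher and 40 lower, among them 39 of the 41, all in their direction. B3galt2 (-0.77, adjusted p = 0.123) and Pmvk were lost.

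**Figure D4:**
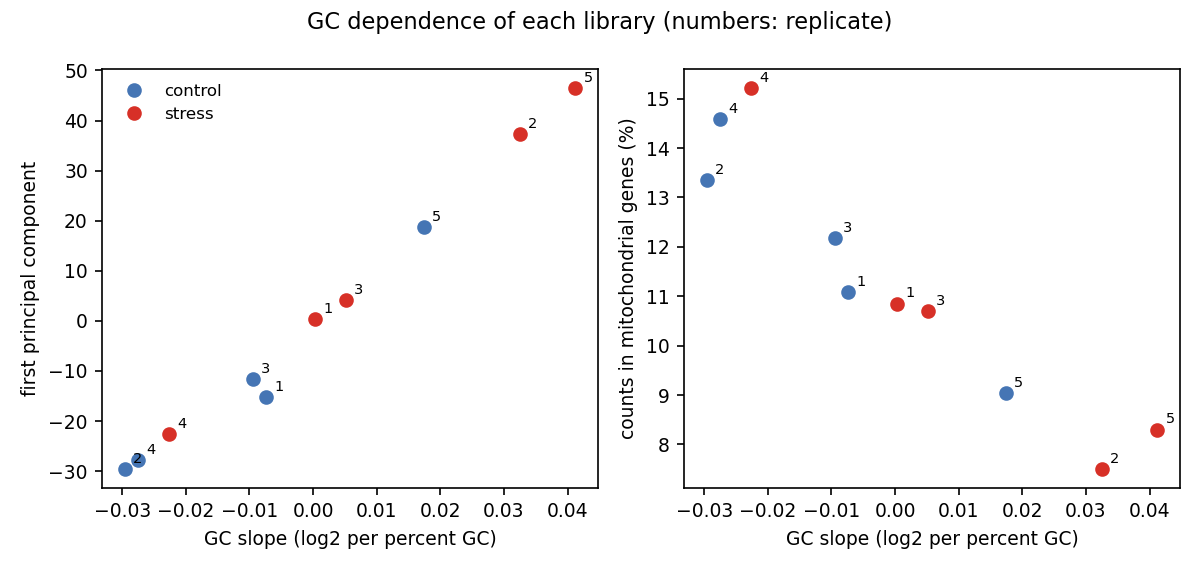
First principal component (left) and share of mitochondrial counts in percent (right) against the slope of log2 CPM on GC content, for 5 control (blue) and 5 stress (red) libraries, numbered by replicate. Both follow the slope, and the groups overlap along it, with control 5 at 0.0174 and stress 4 at -0.0227 log2 per percent GC.

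Summed CPM of markers of other tissues did not pass between the groups after adjustment over the lists. The summed CPM of small intestine genes were 1374 ± 88.1 in controls and 1087 ± 114 under stress (SD, n = 5, exact permutation p = 0.0159, 0.111 adjusted over 14 such lists). Those of anterior and middle Hox genes were 244 ± 16.6 and 269 ± 10.8 (exact permutation p = 0.0159, 0.111 adjusted). The adipocyte sum was 415 ± 158 and 295 ± 137 (exact permutation p = 0.206), and the sum of mesothelial genes 2455 ± 635 and 3298 ± 645 (exact permutation p = 0.0794). Skeletal muscle transcripts were highest in stress 2, with a sum of 406 CPM against 81.9 to 193 CPM in the other libraries. Acta1 was at 24.3 CPM there, against 0.699 to 4.51 CPM in the others. Stress 5 had Hoxd13, a gene of the hindmost gut, at 1.45 CPM against 15.1 to 32.4 CPM in the other stress libraries. Without these 2 libraries 22 genes passed, 10 higher and 12 lower, and 14 of them were among the 41.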

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

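Of the tests here, those of GC content, of a larger share of colonocytes, of exchanged labels for the cholesterol list and of a smaller share of all immune cells were chosen only after the result was seen, as were the fits with a GC correction or without chosen libraries.

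A single library stood apart from the other 4 of its group, by a gap over range above the Dixon critical value for 5 samples, in 15 of 264 groups of values tested, where chance gives about 5%. Stress 5 did so for Gsdmc4 (255 CPM against 393 to 439), Clec2e (56.3 CPM against 74.7 to 83.2), Pmvk (32.1 CPM against 41.8 to 45.2), Hoxd13 (1.45 CPM against 15.1 to 32.4), the cell cycle score (-0.46 against 0.17 to 0.35) and the macrophage score (-0.36 against -0.08 to 0.02). Stress 2 was low for Nr3c1 (64.8 CPM against 87.4 to 98.5), and stress 3 was high for Ms4a1 (7.60 CPM against 3.13 to 3.85). Control 1 was low for Pcna (99.7 CPM against 117 to 124) and Pou2af1 (4.53 CPM against 6.00 to 6.66), and control 2 was high for Plin4 (31.9 CPM against 17.8 to 20.9). Control 3 was high for Reg3b (1567 CPM against 247 to 343) and low in the percentage of reads pseudoaligned (77.2% against 82.0 to 83.8%). Control 5 was low for Tgfb2 (1.27 CPM against 3.14 to 3.84) and high in the summed CPM of the cytosolic ribosomal proteins (21983 against 15773 to 17124).

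The first pattern weighed was the 41 genes past the threshold, a count that 2 of 100 splits of the 10 libraries into 5 and 5 reached, the real one included. After the GC correction 1 of 100 splits, the real one, reached the count of 115, the smallest share possible here, and the highest other gave 96. Counts this high were thus rare among the splits, which argues against chance as the whole cause but does not exclude it. The highest other split without the correction, which exchanges control 5 and stress 4, gave 1679 genes. That split also sorts the libraries by GC slope. Controls 1 to 4 and stress 4 had slopes of -0.0296 to -0.00733 log2 per percent GC, and the other libraries 2.87e-04 to 0.0412. Mitochondrial shares sort the same way (11.1 to 15.2% against 7.51 to 10.85%). The 1679 genes therefore cannot be told apart from that axis and do not by themselves point to exchanged labels. The exchanged split gave 6 lists past the threshold against 14 with the labels as given, but 14 against 16 after the GC correction. The count of lists therefore does not decide between the labels. The lists that separated the groups of the exchanged split were as many as with the labels as given (4 each) before the GC correction. After it they were 3 against 5, the most of all 126 splits. A GC bias that differs between libraries could account for the rise of fold changes with GC content over all genes, since the GC slopes differed by no more than the spread between groups (exact permutation p = 0.159). As the whole cause of the 41 genes, a trend on GC content is argued against by the 39 of them that stayed past the threshold in their direction after the correction. The correction removed only that trend. After it the first principal component still held 26.75% of the variance. On it control 5 (13.4) lay apart from the other controls (-20.2 to -9.97), and stress 4 (-14.65) lay among those. A wider technical difference between libraries along that component is therefore not excluded for the 41 genes. Whether the labels of control 5 and stress 4 were exchanged cannot be told apart from correct labels by these genes. A signature was taken from 127 higher and 43 lower genes found in the other 8 libraries with the GC correction. With those controls averaging 0 and those stress libraries 1, control 5 lay at 0.473 and stress 4 at 0.477, a difference of 0.00415. In those 8 libraries every control had a negative GC slope and every stress library a positive one. The signature may therefore carry that axis too, so a place between the groups decides nothing about the labels. An effect of restraint stays open as a hypothesis.

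The second pattern was the rise of the cholesterol synthesis list. A GC bias as its whole cause is argued against by a mean of 0.61 after the GC correction. A single library is argued against by the score of the list, which separated all 5 stress from all 5 control libraries. The adjusted p was at most 8.84e-12 without any 1 library, but only with the preset correlation of 0.01 (camera). With the estimated correlation of 0.262 the list did not pass even in all 10 libraries (adjusted p = 0.240). A larger share of colonocytes is argued against because the colonocyte list did not rise (mean log2 fold change -0.01, exact permutation p of its score 0.706). The cholesterol score minus the colonocyte score separated the groups (exact permutation p = 0.00794, the smallest possible), which largely repeats the separation by the cholesterol score itself. This list had the smallest p in the other 8 libraries (adjusted p = 1.13e-12, camera with the same preset correlation). On its GC-corrected score control 5 lay at -0.44 and stress 4 at 1.37, each with its own group and 1.81 apart. These positions repeat the separation of the groups by the score, which was known when the test was chosen. Other lists separated the groups of the exchanged split (4 against 4 with the labels as given, and 3 against 5 after the GC correction). The positions therefore do not decide whether the labels were exchanged. A response of colon lipid synthesis to restraint is a candidate explanation, found and tested on the same data, and differences in feeding or in the time of sampling were not tested.

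The third pattern was the fall of the lymphocyte lists, of which the B cell list lost its call without control 5 and stress 4 (adjusted p = 0.243). A GC bias as the whole cause is argued against by means of -0.79 for the B cell list and -0.49 for the T and NK cell list after the GC correction. The T and NK cell score fell more than the macrophage score (exact permutation p = 0.0317, not adjusted). For the B cell score the spread was too wide (exact permutation p = 0.230). The macrophage score was itself lower (exact permutation p = 0.0476, 0.258 adjusted over the lists). A smaller share of all immune cells stays open for both the T and NK cell and the B cell list, because macrophages alone stood for the other immune cells. Marker scores also need not fall in proportion to cell numbers. Fewer lymphoid follicles in the tissue taken stays open, because B and T cell deviations from the group means over the 10 libraries gave r = -0.368 (permutation p = 0.333, rho = -0.406, permutation p = 0.279, r = -0.0388 without the 2 farthest), and 10 libraries are too few to decide. An effect of restraint on lymphocytes may also contribute and was not separated from these.

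For the gene lists as a whole, 10 of 100 splits gave at least 14 lists past the threshold, the highest other split 20, so chance was not excluded for the count of 14. For the 2 fixed genes past the threshold adjusted over the list alone, 2 of 100 splits gave at least 2, and the highest other split also gave 2.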

How the results depend on the processing

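Of the alternatives here, the GC correction, the block with the GC correction, and the fits without stress 2 and stress 5, without the 3 libraries of the steepest GC slope (control 5, stress 2, stress 5) and without control 5 and stress 4 were chosen after the data were seen.

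The count of 41 genes (29 higher, 12 lower) was 41 with DESeq2 size factors, 31 (19 and 12) with upper-quartile scaling, 53 without a filter but 1 count and 31 with at least 1 CPM in 5 libraries. It was 5 (1 and 4) with an offset for transcript length, 4 (0 and 4) on log2(TPM + 0.5) and on log2(TPM + 0.1), 270 (160 and 110) with DESeq2, 314 (168 and 146) with limma voom, 126 (75 and 51) at a threshold of 0.1, and 5 (2 and 3) against a fold of 1.2. It was 115 (75 and 40) with the GC correction, 22 (10 and 12) without stress 2 and stress 5, 59 without the 3 libraries of the steepest GC slope, 961 (654 and 307) without control 5 and stress 4, and 170 (127 and 43) without that pair and with the GC correction. Without 1 library at a time it ranged from 2 (without stress 1) to 100 (without control 5). It was 6 without control 1, 4 without control 2, control 4 or stress 3, and 27 without control 3. It was 32 without stress 2, 89 without stress 4 and 23 without stress 5. The cause was not tested, apart from the fewer samples of these fits. Of the 41 genes, 2 stayed past the threshold without any 1 library, the median gene did so in 4 of 10 such fits, and 0 changed sign.

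The count of 14 lists was 0 with an estimated correlation, in the main setting and, as added after the data were seen, in each other setting that gave list means of its own. It was 3 with fry. When only the cell type lists were tested and adjusted, 5 passed, the same cell type lists as in the main test. In the other settings the count was 11 to 18, and 10 to 14 without 1 library at a time. Without control 5 and stress 4, calls were lost by the cell cycle (adjusted p = 0.149), B cell (0.243), fatty acid oxidation (0.204), adipocyte (0.187), plasma cell (0.241) and extracellular matrix (0.204) lists. The length offset ended those of the adipocyte (0.0768), plasma cell (0.0577) and hypoxia (0.0768) lists, log2(TPM + 0.5) those of the adipocyte (0.0665) and hypoxia (0.0671) lists, the block that of the matrix list (0.0707), leaving out stress 2 and stress 5 those of the matrix (0.0509) and hypoxia (0.337) lists, and leaving out the 3 steepest libraries those of the MHC class II (0.144, mean -0.24), matrix (0.126) and hypoxia (0.144) lists. The count of 2 fixed genes past the threshold adjusted over the list alone was 1 with the GC correction, without stress 2 and stress 5, and without control 5 and stress 4 with the GC correction, and 1 to 3 without 1 library at a time. Tnf passed in each of these fits.

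With the replicate number as a block, 84 genes (53 and 31), 14 lists and 1 fixed gene passed, and with the GC correction as well 79 genes (52 and 27), 15 lists and 1 fixed gene. The numbers were not taken to pair the libraries, because the labels do not say that they do. Deviations of same-numbered libraries correlated at 0.0479, -0.221, -0.00667, 0.444 and 0.339, and 4 of 10 libraries correlated best with their own number, before and after the GC correction. These values do not settle whether the numbers mark pairs.

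Values that changed sign were all near 0 and not past a threshold. Without 1 library at a time the highest mean of the smooth muscle list was 0.0539 and the highest value of Nos1 was 0.163, both without stress 1. The mean of the smooth muscle list was -0.0144 with upper-quartile scaling, -7.26e-05 with at least 1 CPM in 5 libraries, -0.0488 without control 4, -3.37e-04 without control 5, -0.00670 without stress 2, -0.0132 without stress 3, -0.0129 without stress 5, -0.0583 with the GC correction, -0.0573 with block and GC correction, -0.0524 without stress 2 and stress 5, -0.0606 without the 3 steepest libraries and -0.0964 without control 5 and stress 4 with the GC correction. Nos1 was at -0.0784 with the length offset, -0.0236 on log2(TPM + 0.5), -0.0466 on log2(TPM + 0.1), -0.0419 without control 4, -0.00570 without control 5, -0.0676 without stress 5, -0.0705 with limma voom, -0.0688 with the GC correction, -0.0555 with block and GC correction, -0.132 without stress 2 and stress 5, -0.156 without the 3 steepest libraries, -0.0221 without control 5 and stress 4 and -0.170 without that pair with the GC correction. Per1 was at -0.0199 with the length offset, -0.0351 on log2(TPM + 0.5), -0.0393 on log2(TPM + 0.1), -0.173 with the GC correction, -0.218 with block and GC correction and -0.211 without control 5 and stress 4 with the GC correction. The mean of the clock list was -0.00231 with the GC correction, -0.0100 with block and GC correction and -0.0433 without control 5 and stress 4 with the GC correction; without that pair the enteric glia list was at 0.0182, and with the GC correction as well Nr3c1 was at 0.00675. The cause was not tested.

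Depth limits the low genes: with 2100452 reads, stress 5 had a floor of 1.44 CPM for a count of 0, close to the control mean of Tnf.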

Other observations

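The gene lists described first were fixed before the data were examined, the genes named from them were chosen after their values were seen, and the lists of the 3 hypotheses at the end were written after the main results and before their own values were seen.

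Genes of the circadian clock moved apart from one another. Per2 and Per3 rose, while Arntl, whose product drives them, had a log2 fold change of -0.64 (adjusted p = 0.0712, edgeR) and passed after the GC correction (-0.62). Adjusted over the list alone, 4 of the 18 clock genes rose and 1 fell, and Dbp had a log2 fold change of 0.14. Of the defence list, the lectin gene Itln1 (-2.76, adjusted p = 0.0621) and the ribonuclease gene Ang4 (-2.90, adjusted p = 0.145) fell when adjusted over the list alone, opposite to Reg3b and Nos2, and Itln1 passed over all genes after the GC correction (-2.81).

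Immunoglobulin genes and segments, counted as a class, were lower in 31 of 41 tested (median -0.46), with 0 past the threshold over all genes. The summed CPM of neutrophil markers were 55.1 ± 21.3 in controls and 103 ± 38.3 under stress (SD, n = 5, exact permutation p = 0.0714, 0.278 adjusted over 14 lists), nearly all of it Ly6g (51.1 and 98.6 CPM), while S100a8 and S100a9 were at 0.188 CPM or less in either group mean.

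A first hypothesis was that the rise of sterol genes is part of a wider rise of lipid synthesis. The score of 14 fatty acid synthesis genes whose values had not been seen separated the groups, before and after the GC correction. The mean log2 fold change of these genes was 0.20, and 12 were positive. The exact permutation p was 0.00794, the smallest possible, and 0.0198 adjusted over 5 tests. With an estimated correlation the list had an unadjusted p of 0.00393 (camera). The cholesterol synthesis list had an unadjusted p of 0.00470 in that test and did not pass after adjustment over the lists (adjusted p = 0.240). The value of 0.00393 was not adjusted over lists, so it does not set this list above the cholesterol list. Singly, 0 genes were past the threshold. At an unadjusted p under 0.05, 7 genes were higher and 1, Acsl3, was lower (-0.38). Apart from Acsl3, this is consistent with the hypothesis.

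A second hypothesis, from Mcm5, Lig1, Dnmt1 and Uhrf1, was that S phase transcripts rose more than those of G2 and M phase. Of 22 further S phase genes 20 were positive and their score separated the groups (exact permutation p = 0.00794, the smallest possible, 0.0198 adjusted), and 21 G2 and M phase genes gave an exact permutation p of 0.841. The difference of the scores, 0.24, did not pass (exact permutation p = 0.135, 0.179 adjusted), so that a difference between the phases may exist but was not shown.

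The third hypothesis was that the falls of the Gsdmc genes and Pla2g4c could reflect a lower response of the epithelium to type 2 cytokines, which induce Gsdmc genes. The score of 8 tested genes of that response did not pass (exact permutation p = 0.143, 0.179 adjusted). Of the 8 genes 1, Gsdmc (-0.98), belongs to the family that prompted the hypothesis and is no independent evidence for it, so that the hypothesis stays open without support from this test.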
